A study of Mus musculus with 7 samples.

How the data were processed

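Gene expression was measured in GFP-positive osteoblasts sorted from single mice, 4 bearing lung tumors and 3 tumor-free, with 1 library per mouse. Per the labels' protocols, RNA of 2000 sorted cells was extracted with Trizol and made into libraries of transcript 3′ ends by a customised CEL-Seq method with unique molecular identifiers. The submitters' processing notes name TopHat2 2.0.10, SAMtools and the mouse build mm10. The program that counted, its annotation and strand setting, and whether identifiers were collapsed are not given in the sources used here. The deposited values are whole-number counts per Entrez gene ID, 1 file per mouse, not normalized, with a different total in each library. Because the files do not state whether a count is a read or a distinct molecule, counting errors are given as errors of counts only.

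Each file listed the same 23725 gene IDs. A RefSeq table of assembly GRCm38.p6, the same assembly as mm10, gave a symbol, a biotype and coordinates to 23666 of them; the other 59 kept their IDs, and held between 0.0817% and 0.155% of the counts of a library. No gene of the mitochondrial chromosome was among the IDs, so the share of mitochondrial transcripts was not used. In all 7 libraries 10381 genes had 0 counts. No library repeated another: for each pair the chi-square per degree of freedom over genes lay between 3.59 and 7.07, far above counting noise.

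Groups were taken from the sample labels. The design text states matching for age, sex and litter; age is the only one of these that varies in the labels, and it entered the model as a factor with 2 levels. Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 2495 genes holding 84.2% to 87.8% of each library's counts. Libraries were scaled by TMM (factors 0.945 to 1.05). Differences were tested with glmQLFit (robust, without the legacy option) and glmQLFTest in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg at 0.05. Log2 fold changes are tumor-bearing over tumor-free, with a prior count of 0.125, and CPM were computed on TMM-scaled library sizes. Shares of counts are on unscaled totals.

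Before the data were examined, 52 gene lists, the rule for named genes, the tests and most alternatives were fixed. The lists with at least 5 genes tested, 18 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, then with an estimated correlation and with fry; the other 34 had too few genes tested. Members of a list were also adjusted over the list alone. The named genes were up to 8 per direction with the smallest p when fewer than 5 passed, leaving out unnamed gene models; up to 4 members with the smallest p in each list past the threshold and in the osteoblast, niche, chemokine and RAGE lists; and the osteocalcin genes, Ptprc, Pecam1, Ager, Csf3, Cxcl12, Xist and Trp53. Some genes that the rule takes are not reported here. Other genes named for the highest counts or as cell markers were chosen after their values were seen. Trp53 had 0 to 1 counts per library. Library totals and shares of 19 cell type lists, and of the other lists adjusted among themselves, were compared by two-sided exact permutation tests over the 35 splits of 7 libraries into 4 and 3.

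Alternatives were: no age term, 31-week mice only, the replicate number as a block, DESeq2 1.42.0, limma voom with quality weights, RLE and upper-quartile scaling, total counts only, no filter, a stricter filter (30 counts in at least 3 libraries), no robust estimation, removal of haemoglobin, immunoglobulin and related genes, and each library left out in turn. The block fit had no age term and left out tumor-bearing replicate 4, which has no tumor-free partner number. Its replicate 3 joined a 31-week tumor-bearing with a 23-week tumor-free mouse. After seeing the data, a legacy quasi-likelihood fit and a fit without genes with a mean count over 100 were added. A covariate of ribosomal protein and oxidative phosphorylation counts, in place of age, was also added for camera. The procedure was tested on simulated counts for the 2495 genes, with 200 genes changed by 2-, 4- or 8-fold in 5 simulations each; the share of calls that were false was at most 4.06%. For lists of 8 genes, a list changed 1.5-fold was called in 4 of 10 simulations and one changed 2-fold in 8 of 10. Unchanged lists were called 1 time with no list changed, 1 time at 1.5-fold and 2 times at 2-fold, over 10 simulations each. Genes were simulated independently, so these simulations do not test the preset correlation.

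Sequence features came from the longest GENCODE vM21 transcript of each symbol, available for 97.1% of genes. A-rich windows held at least 11 A in 12 bases, leaving out the last 100 bases; shared 25-mers were those found, on either strand, in transcripts of at least 50 genes, leaving out those with at least 23 bases of 2 kinds. Opposite-strand partners were genes with an exon overlapping the last 500 bases. Random draws (10000) were matched on deciles of transcript length. These steps used Python 3.11.15, pandas 2.3.3 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9.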

Results

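Osteoblasts, the bone-forming cells that secrete and mineralise bone matrix, were profiled in mice carrying an osteocalcin-driven GFP reporter. In these mice adenovirus expressing Cre recombinase, delivered to the airways, starts lung adenocarcinoma. The comparison asked whether a lung tumor is accompanied by a change of gene expression in osteoblasts of distant bone. GFP-positive cells lacking the surface proteins of leukocytes, endothelium and erythroid cells were sorted from pooled bone digest and marrow, 2000 cells per mouse. Libraries came from 4 tumor-bearing mice, taken 14 weeks after the virus, and 3 tumor-free mice, 1 library per mouse and all recorded as male. Tumor-bearing replicate 4 and tumor-free replicate 3 were 23 weeks old and the other mice 31 weeks.

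Total counts ranged from 77127 in tumor-bearing replicate 1 to 169774 in tumor-bearing replicate 3. The other tumor-bearing libraries held 98499 (replicate 2) and 141564 counts (replicate 4), and the tumor-free libraries 102144, 122911 and 118654 counts in replicates 1 to 3. Mean depth was 121741 ± 41756 counts (SD, n = 4) with a tumor and 114570 ± 10969 counts (SD, n = 3) without, a difference within the spread (two-sided exact permutation test over 35 splits, p = 0.800; smallest possible p = 0.0286). Between 6044 and 9273 of the 23725 genes had at least 1 count in a library. At these depths 3 counts, the limit that a count of 0 allows, correspond to 17.7 CPM in the deepest and 38.9 CPM in the shallowest library.

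Transcripts of the osteoblast lineage were present in every library, but at low counts. Col1a1 (chromosome 11, 94936224 to 94953042, mm10), encoding a chain of type I collagen, the main protein of bone matrix, had 23 to 96 counts per library. Col1a2, the partner chain, had 11 to 31 counts, the matrix protein genes Sparc and Ibsp had 14 to 70 and 10 to 51, and Runx2, the transcription factor that specifies osteoblasts, had 7 to 35. Osteocalcin, whose promoter drives the reporter, was near the limit of detection: Bglap (chromosome 3, 88383495 to 88384466) had 0 to 2 counts, and its near-identical neighbours Bglap2 and Bglap3, with which reads can be shared, had 0 to 1 each. Alpl (1 to 7 counts) and Sp7 (0 to 2) were also sparse.

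Marker transcripts of leukocytes, which the sort excluded, were uneven. Pecam1, which encodes the endothelial protein CD31, had 0 counts in all 7 libraries. Ptprc, which encodes CD45, had 0 to 2 counts. The abundant neutrophil and macrophage transcripts S100a8, Elane and Lyz2 had 0 counts everywhere. Itgam, an integrin of myeloid cells, had 19 to 45 counts. The mature neutrophil and monocyte lists had a median count of 0 per gene, but their mean counts of 13 and 14.0 per gene and library stood at percentiles 99.9 and 99.3 of random lists matched on transcript length. The osteoblast matrix list had a mean of 8.54 (percentile 85.8), osteocyte genes 4.51 (47.7), fibrillar collagens 6.83 (43.3) and endothelial markers 1.83 (7.62). In each of the neutrophil and monocyte lists 1 gene weighed heavily in the mean. Cxcr2 had a mean of 186 counts per library among 31 neutrophil genes, and Ms4a6c 195 among 30 monocyte genes. The highest counts fell on genes with no known part in bone formation. Kcnq1ot1, a long non-coding RNA that lies antisense to Kcnq1 (chromosome 7, 143213111 to 143296547; the strand setting of the counts is not given in the sources used here), had 279 to 303 counts per library and ranked first. H2-Q4 (193 to 261 counts), Ms4a6c (150 to 244) and Cxcr2 (143 to 229), all better known from leukocytes, were among the 14 genes with most counts. Transcripts of H2-Q4, Ms4a6c and Cxcr2 hold short sequences shared by transcripts of many genes. Whether their counts, and the high means of the neutrophil and monocyte lists, came from leukocyte RNA was not tested. Abundant housekeeping transcripts ranked lower, with 79 to 258 counts for Actb, 2 to 15 for Gapdh and 0 to 6 for Rplp0. The highest count of any gene lay between 282 and 303 in each library, although the totals differed 2.20-fold.

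**Figure D1:**
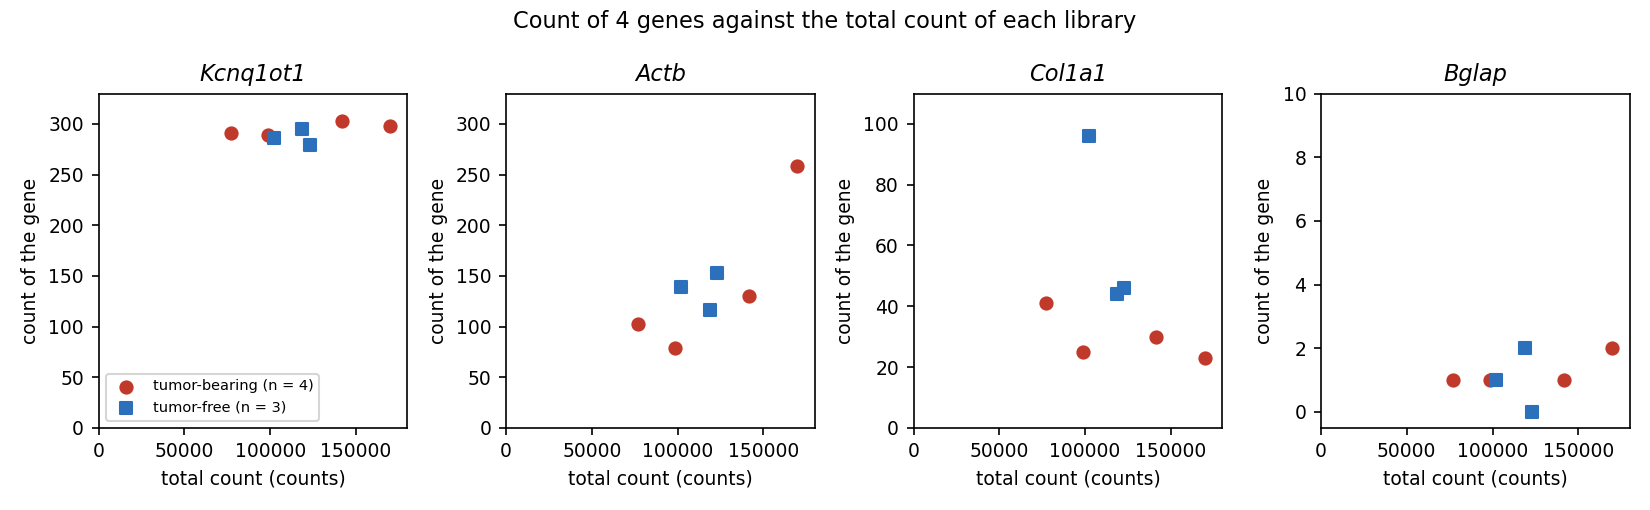
Count of Kcnq1ot1, Actb, Col1a1 and Bglap (vertical axes, counts) against the total count of each library (horizontal axes, counts), with circles for the 4 tumor-bearing and squares for the 3 tumor-free libraries. Kcnq1ot1 stayed between 279 and 303 counts at every depth, and Bglap between 0 and 2.

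No single gene passed the test between osteoblasts of tumor-bearing and tumor-free mice, and 5 gene lists were called lower with a tumor only where a small preset correlation between genes was assumed. The lists were cytosolic ribosomal proteins, the response to parathyroid hormone (PTH) and vitamin D, signalling by BMP and TGF-beta, osteoblast matrix and mineralization, and the unfolded protein response. All 5 were on the lower side, out of 18 lists with at least 5 genes tested, and no list was called higher (camera with a preset correlation of 0.01, Benjamini-Hochberg over the lists). All 5 calls were lost when the correlation between genes was estimated for each list (adjusted p = 0.207 for each with an estimated correlation). The rotation test fry, which asks whether a list's genes move one way on balance, called 0 of the 18 lists (lowest adjusted p = 0.123). By the exact permutation test on the summed share of counts of each whole list, the p of the 5 lists lay between 0.0571 and 0.486 (adjusted 0.457 to 0.818). The smallest possible p of this test is 0.0286, so 1 list alone could not have passed its adjustment. With no low count filter camera called 0 lists. The number of lists was 1 without tumor-free replicate 1, 2 without tumor-bearing replicate 3 and 3 without tumor-bearing replicate 2.

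The osteoblast matrix and mineralization list fell with a median log2 fold change of -0.45 over 10 genes tested (camera adjusted p = 0.00890; with an estimated correlation adjusted p = 0.207), 8 of them below 0 and 2 above. With no low count filter the call was lost, with a median of -0.05 and a mean of 0.00587 over 27 members. Pth1r (chromosome 9, 110722085 to 110747145), the receptor through which PTH acts on osteoblasts, had 162 ± 15.6 CPM in tumor-bearing (SD, n = 4) and 238 ± 22.2 CPM in tumor-free mice (SD, n = 3), and each of the 4 tumor-bearing libraries lay below each of the 3 tumor-free ones (log2 fold change -0.52, SE 0.24). Col1a1 had 289.7 ± 189.8 against 559.6 ± 324.6 CPM (-1.06, SE 0.52) and Col1a2 162 ± 47.1 against 231 ± 29.8 CPM (-0.53, SE 0.31). Tumor-free replicates 1 to 3 had 934, 390 and 355 CPM of Col1a1, and the tumor-bearing libraries 129 to 562 CPM. Bmp3, a negative regulator of bone density, had 83.4 ± 35.5 against 129 ± 21.4 CPM (-0.59, SE 0.40), and Ibsp lay on the other side (0.21, SE 0.46). None of these members passed edgeR's quasi-likelihood test, over all genes or adjusted over the list alone. The call of the list was lost without tumor-free replicate 1 (median -0.26) and without tumor-bearing replicate 2 (median -0.34), and with the ribosomal protein and oxidative phosphorylation covariate.

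The PTH and vitamin D response list fell with a median of -0.48 over 6 genes (camera adjusted p = 0.000320; with an estimated correlation adjusted p = 0.207), all 6 of them below 0, and was the only list past the threshold whichever of the 7 libraries was left out. With no low count filter the call was lost, with a median of -0.12 over 24 members. Fos, an immediate early gene that PTH induces but that tissue digestion also induces, had 63.2 ± 45.0 CPM with and 191 ± 115 CPM without a tumor (log2 fold change -1.28, SE 0.54). Sik1, a kinase of the salt-inducible family whose activity PTH signalling restrains, had 482 ± 198 against 868 ± 469 CPM (-0.79, SE 0.35). Its transcript level does not measure that activity. Tumor-free replicates 1 to 3 had 875, 1333 and 395 CPM of Sik1, and the tumor-bearing libraries 336 to 770 CPM. Igf1, an anabolic growth factor of bone, had 278 ± 49.4 against 385 ± 167 CPM (-0.45, SE 0.34). Its tumor-free values were 574, 323 and 258 CPM in replicates 1 to 3, and the tumor-bearing libraries had 236 to 348 CPM. Pth1r belongs to this list too, and Igf1 and Pth1r also to the niche list below, so the lists are not independent. No member passed adjusted over the list alone (lowest adjusted p = 0.132, edgeR) or over all genes.

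The BMP and TGF-beta list fell with a median of -0.59 over 7 genes (camera adjusted p = 0.00775; with an estimated correlation adjusted p = 0.207), 5 below 0 and 2 above. With no low count filter the call was lost, with a median of -0.42 over 26 members. Ltbp1, which anchors latent TGF-beta in the matrix, had 273 ± 91.3 CPM with and 486 ± 149 CPM without a tumor (log2 fold change -0.80, SE 0.33). Tgfb3, a TGF-beta ligand, lay on the same side (-0.67, SE 0.45). Smad7, a feedback inhibitor of the pathway, had 83.1 ± 42.4 against 339 ± 400 CPM (-1.81, SE 0.71), with 94 of its 164 counts in tumor-free replicate 2. No member passed over all genes or adjusted over the list alone (edgeR). The call was lost without tumor-free replicate 1 (median -0.47) and without tumor-free replicate 2 (median -0.20), and too few members were tested without tumor-bearing replicate 3.

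Ribosomal protein genes fell with a median of -0.73 over the 10 tested of 80 (camera adjusted p = 0.000320; with an estimated correlation adjusted p = 0.207), 8 below 0 and 2 above. With no low count filter the median was -0.35 over 77 members and the call was lost. The summed level of all 80 genes was 3196 ± 1026 CPM with and 3609 ± 700.4 CPM without a tumor (log2 ratio -0.18, exact permutation p = 0.486). Rpsa had 96.1 ± 33.4 CPM with and 240.4 ± 92.4 CPM without a tumor (log2 fold change -1.25, SE 0.38), and Rpl4 49.4 ± 26.3 against 115 ± 33.4 CPM (-1.23, SE 0.40); for both, the 4 tumor-bearing libraries lay below the 3 tumor-free ones. Rps2 (-0.74, SE 0.34) lay on the same side and Rps15a on the other (0.64, SE 0.53). Many ribosomal protein genes have processed pseudogenes that can share their reads. No member passed over all genes or adjusted over the list alone (edgeR). The call was lost without tumor-free replicate 1 (median -0.20) and without tumor-bearing replicate 3 (median -0.76, 9 genes).

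The unfolded protein response list fell with a median of -0.83 over 5 genes (camera adjusted p = 0.0258; with an estimated correlation adjusted p = 0.207), 4 below 0 and 1 above. With no low count filter the call was lost, with a median of -0.34 over 24 members. Hyou1, a chaperone of the endoplasmic reticulum, had 198 ± 103 CPM with and 459 ± 169 CPM without a tumor (log2 fold change -1.20, SE 0.38). Sdf2l1, a chaperone cofactor, had 134 ± 58.9 against 540.0 ± 763 CPM (-1.71, SE 0.98), with 146 of its 242 counts in tumor-free replicate 1, and its log2 fold change was 0.49 without that library. Sel1l, which serves the degradation of misfolded proteins, had a log2 fold change of -0.83 (SE 0.69), and the disulphide isomerase gene Pdia4 one of 0.32 (SE 0.42), or -0.13 without tumor-bearing replicate 2. No member passed over all genes or adjusted over the list alone (edgeR). The call was lost without tumor-free replicate 1 (median -0.16), tumor-bearing replicate 2 (median -0.47) or tumor-bearing replicate 3 (median -1.08). It was also lost with no age term (median -0.55) and with the replicate number as a block (median -0.21). The ribosomal protein and oxidative phosphorylation covariate, which took the place of age, lost the call too.

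**Figure D2:**
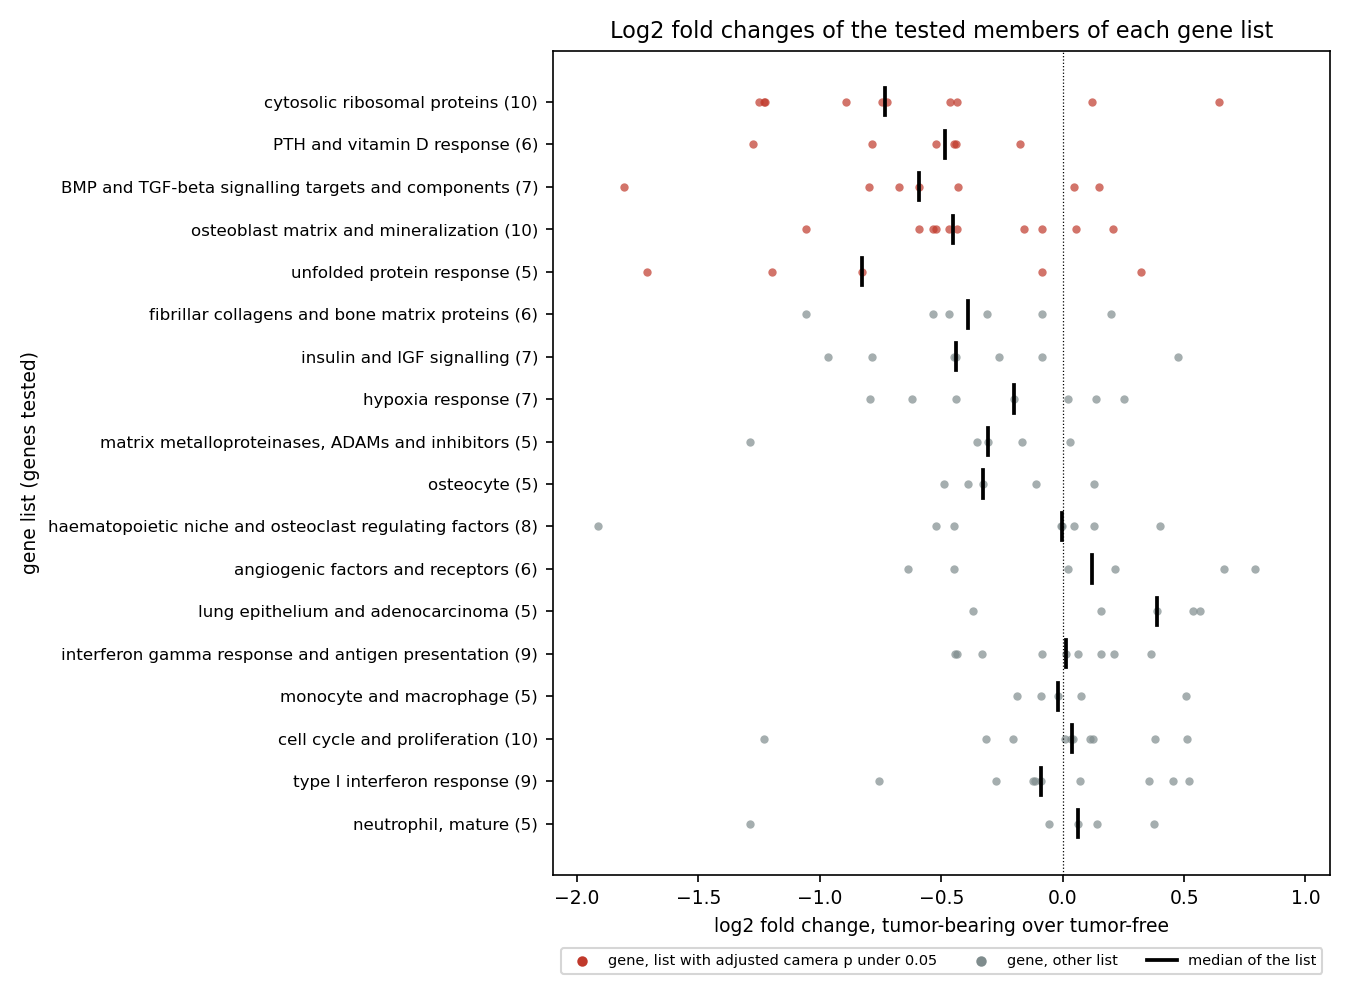
Log2 fold change, tumor-bearing over tumor-free (horizontal axis), of each tested gene (points) in the 18 gene lists (vertical axis, number of genes tested in parentheses), with the list median as a vertical bar. The 5 lists with a camera adjusted p under 0.05, in red, have medians between -0.83 and -0.45.

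Over the 2495 genes tested, edgeR's quasi-likelihood test with age in the model called 0 genes higher and 0 lower in tumor-bearing mice (lowest adjusted p = 0.990). At an unadjusted p under 0.05 there were 67 genes, 25 higher and 42 lower, where chance alone would give 124.8. DESeq2 also called 0 genes (13 higher and 36 lower unadjusted), as did limma voom (58 higher and 47 lower unadjusted). The groups did not overlap for 88 genes, 3.53% of those tested, against 5.71% by chance. The genes with the smallest p on the higher side included Cacnb4, a calcium channel subunit, with 422 ± 283 against 73.5 ± 30.5 CPM (log2 fold change 2.30, SE 0.62), Bloc1s6 (1.04, SE 0.29), Myo3b (1.30, SE 0.40), Slc12a8 (0.90, SE 0.28), Rcbtb1 (1.03, SE 0.33), Camk2a (1.07, SE 0.36) and Zfp446 (0.79, SE 0.30). Icos, a T cell costimulator, had the largest value of these (3.46, SE 1.11), with 227 of its 271 counts in tumor-bearing replicate 4. On the lower side stood Ms4a6b (35.1 ± 15.8 against 131 ± 37.8 CPM; -1.75, SE 0.42), Klf13 (-1.06, SE 0.29), Agpat1 (-0.83, SE 0.24), H2ac23 (-2.39, SE 0.72) and Ggact (-0.76, SE 0.24), besides Rpsa and Hyou1. Bet1l (-2.88, SE 0.80) had 219 of its 332 counts in tumor-free replicate 2. None of these genes passed the adjusted threshold (adjusted p = 0.990 each, edgeR).

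The precision of single genes was low. The median SE of the log2 fold change was 0.34, and the median 95% interval reached 0.78 to either side. Counts were simulated for these 2495 genes at the same depths and spread. Of the changed genes that passed the low count filter again, 0.112% at 2-fold, 22.1% at 4-fold and 88.5% at 8-fold were recovered. Changed genes that the filter removed are not in these shares. Most changes of 2-fold and 4-fold would therefore have been missed with these libraries.

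**Figure D3:**
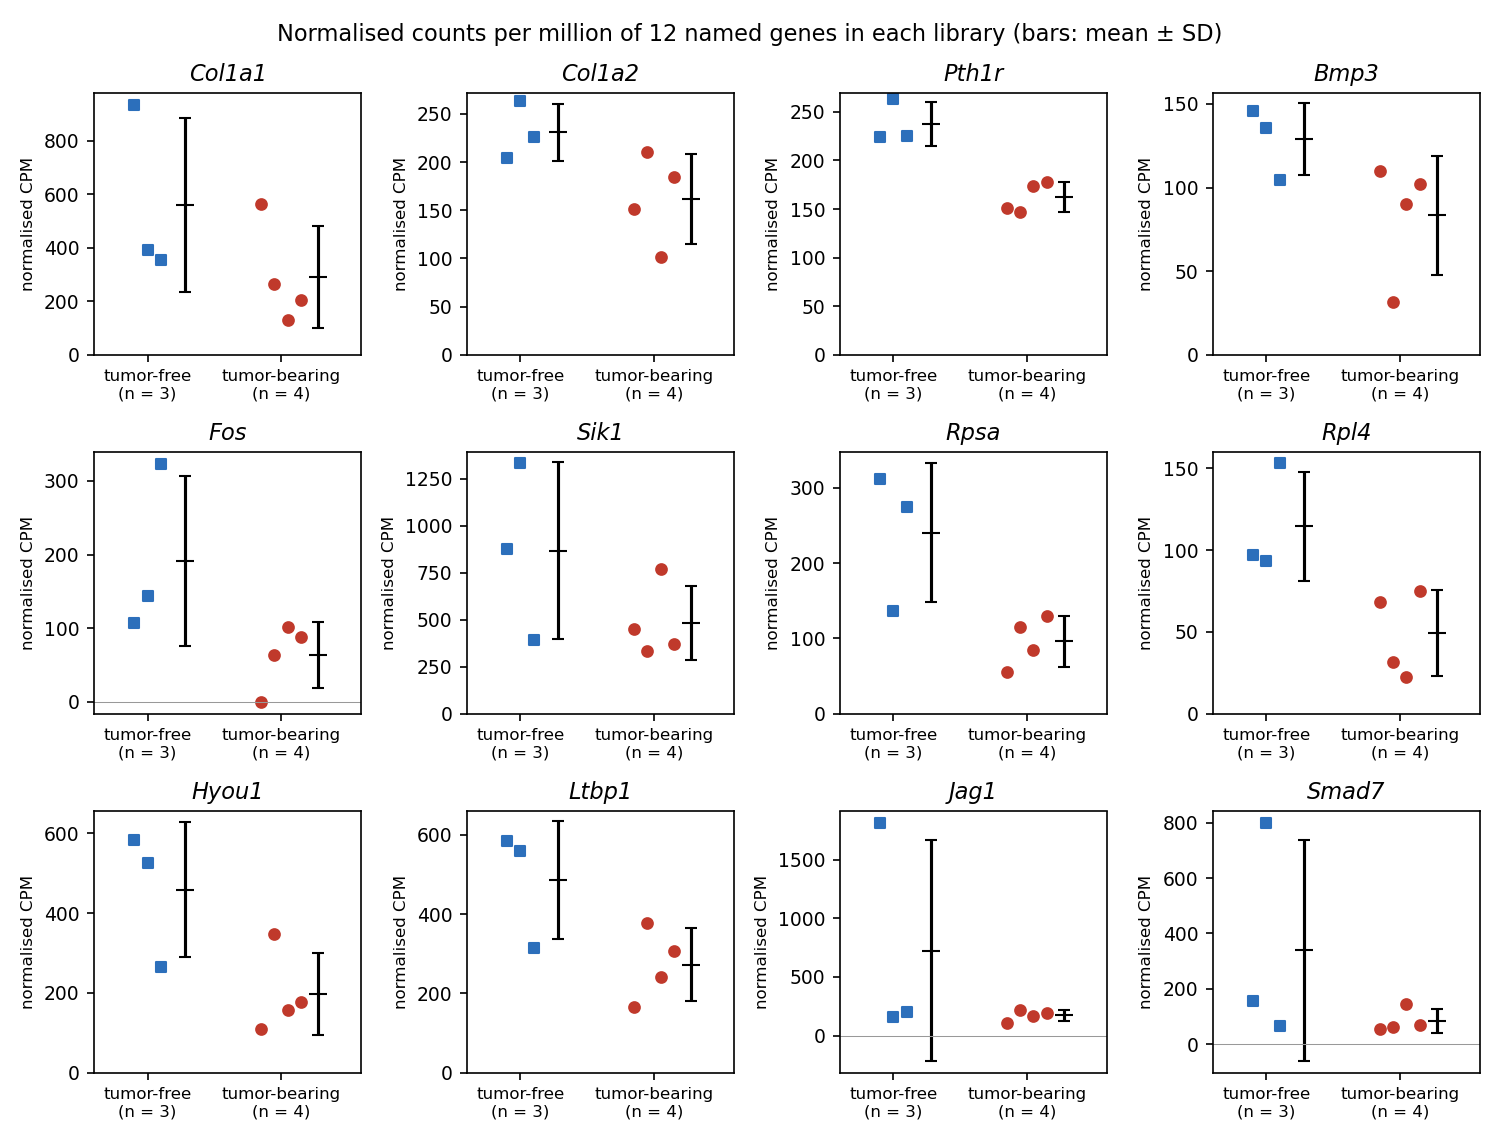
Normalised CPM (vertical axes) of 12 named genes in each tumor-free (squares, n = 3) and tumor-bearing (circles, n = 4) library, with the mean ± SD beside each group. For Pth1r, Fos, Rpsa and Rpl4 the 4 tumor-bearing libraries lie below the 3 tumor-free ones, and for Jag1 and Smad7 a single tumor-free library stands above the rest.

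Of 35 genes listed for the action of osteoblasts on blood formation and on osteoclasts, 8 could be tested, and these did not pass as a list. Kitl, Csf1 and Tnfsf11 were among the members with too few counts to test. The median of this niche list was -0.00460 over 8 genes tested and its mean -0.29 (camera adjusted p = 0.391), and no member passed over all genes or adjusted over the list alone (edgeR). Lepr, the leptin receptor that marks stromal cells of the marrow niche, had 813 ± 129 CPM with and 617 ± 61.7 CPM without a tumor (log2 fold change 0.40, SE 0.21). Jag1, a Notch ligand, had 171 ± 47.2 against 724 ± 940.1 CPM (-1.91, SE 0.85), with 186 of its 316 counts in tumor-free replicate 1, and its log2 fold change was 0.01 without that library. Cxcl12, which retains haematopoietic cells in the marrow, had 1 to 4 counts per library. Csf3, the granulocyte colony-stimulating factor that drives neutrophil production, had 0 counts in all 7 libraries, and so had Cxcl1 and Il6.

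Of the chemokines and growth factors that attract or expand neutrophils and monocytes, Ccl9 was the only gene tested. It had 132 ± 24.7 CPM with and 138 ± 35.8 CPM without a tumor (log2 fold change -0.01, SE 0.30), and the sign turned in several fits, 3 of them with 1 library left out. Ager, which encodes the receptor RAGE, had 0 counts in every library. Among RAGE ligands and partners, Hmgb2 had 159 ± 43.2 against 386 ± 244 CPM (-1.23, SE 0.52), S100b 374 ± 250.3 against 506 ± 599 CPM (-0.59, SE 0.62), Hmgb1 218 ± 139.6 against 207 ± 101 CPM (-0.03, SE 0.42) and Itgam 266 ± 13.2 against 257 ± 61.4 CPM (0.06, SE 0.27); none passed over all genes or adjusted over the list alone (edgeR). S100b had 141 of its 347 counts in tumor-free replicate 2, and its log2 fold change was 0.61 without that library and 0.42 with the replicate block. Hmgb1 and Itgam also turned direction without tumor-free replicate 2 (0.21 and -0.16) and without tumor-bearing replicate 2, Hmgb1 also with no age term and with the replicate block. Hmgb1 and Hmgb2 have pseudogenes that can share their reads. Fewer than 5 genes of the chemokine and RAGE lists were tested, so neither list had a camera test.

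The share of counts on marker lists of 19 other cell types did not separate the groups. By the exact permutation test 0 of the 19 lists passed after adjustment (lowest adjusted p = 0.971), 0 at an unadjusted p under 0.05, and 0 without the most abundant gene of each list. The smallest possible p of this test is 0.0286, so a list by itself could not have passed the adjustment, and the unadjusted p are the more telling. Mature neutrophil markers took 0.342% ± 0.0504 of counts with a tumor (SD, n = 4) and 0.346% ± 0.0395 without (SD, n = 3). Monocyte and macrophage markers took 0.357% ± 0.0345 and 0.361% ± 0.0270, and osteoclast markers 0.0677% ± 0.00703 and 0.0551% ± 0.0112. Markers of lung epithelium and adenocarcinoma took 0.175% ± 0.0445 and 0.162% ± 0.00545.

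Whether the tumor effect differed between ages could not be decided. At 23 weeks there was 1 mouse per group, so the spread behind an age-by-tumor term came from the 31-week mice alone. Among the 31-week mice alone, 3 with and 2 without a tumor, edgeR called 0 genes (11 higher and 71 lower unadjusted).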

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

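Except for the counts of lists over all 35 splits, the oxidative phosphorylation sums and the slopes of genes with moderate counts, the tests in this part were chosen after the result was seen. A tumor-bearing library stood apart from the other 3 in 7 of 60 values examined, where chance gives about 1 in 20. Icos had 1549 CPM in tumor-bearing replicate 4 and 21.0 to 135 CPM in the others. Pdia4 had 473 CPM in tumor-bearing replicate 2 against 165 to 191 CPM. Hmgb2 had 94.6 CPM in tumor-bearing replicate 2 against 178 to 184 CPM. Smad7 had 146 CPM in tumor-bearing replicate 3 against 54.9 to 68.2 CPM. Chondrocyte markers took 0.388% of counts in tumor-bearing replicate 2 (95% Wilson interval 0.351% to 0.429%) against 0.197% to 0.218%. In tumor-bearing replicate 4, endothelial markers took 0.0650% (0.0530% to 0.0797%) against 0.0259% to 0.0271%, and pericyte and smooth muscle markers 0.147% (0.128% to 0.168%) against 0.0376% to 0.0448%.

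Across the 35 splits of the 7 libraries into 4 and 3, the real split gave 0 genes, a count that all 35 must reach, so the comparison decides nothing; the highest of the others gave 16. That split set tumor-bearing replicates 1 and 3 with tumor-free replicates 1 and 2, all 31 weeks old. For the 5 lists that were lower in tumor-bearing mice, 2 of the 35 splits gave as many, the real split and another with 6 lists. The other split set both 23-week mice with tumor-free replicates 1 and 2, against tumor-bearing replicates 1 to 3. With age in the model, it repeats the real comparison among the 31-week mice with the sign turned, so it does not speak for chance. Among the 20 splits that part the 23-week mice, only the real split reached 5 lists, and the highest other gave 4. With 20 splits the smallest possible share is 1 in 20, which cannot fall under 0.05, so chance cannot be excluded. A single library does not account for the PTH and vitamin D list, which passed in 7 of 7 fits with 1 library left out, but may account for ribosomal proteins, osteoblast matrix and the unfolded protein response, with medians of -0.20, -0.26 and -0.16 without tumor-free replicate 1. Of the 4 other lists 0 passed without that library, but the BMP and TGF-beta median was still -0.47 there, and -0.20 without tumor-free replicate 2. A smaller share of abundant messenger RNA in the tumor-bearing libraries cannot be told apart, because the sums of oxidative phosphorylation genes differed by a log2 ratio of -0.00626 with a within-group SD of 0.14 on few counts. An effect of the tumor on osteoblasts stays open beside these. The labels give a time after the virus for the tumor-bearing mice only, so an effect of the virus itself cannot be told apart from one of the tumor.

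The highest counts fell on genes without a known osteoblast role. Assignment of reads to the opposite strand cannot be told apart: the partner had more counts in 27.3% of 11 pairs of ribosomal protein or oxidative phosphorylation genes and their opposite-strand genes, but in 8 pairs both genes had fewer than 10 counts per library, and in the other 3 the partner had more. Repeats are a candidate source: 62% of the 100 genes with most counts held a 25-mer found in transcripts of at least 50 genes, against 24% in random draws matched on length (central 95% 16% to 32%). Priming at A-rich stretches cannot be told apart, because the mean Spearman rho within length deciles, across genes that are not independent replicates, was 0.161 for A-rich and 0.166 for T-rich windows. No biological explanation was tested.

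The highest count of any gene in a library, 282 to 303, hardly rose with depth. Counts of the genes with most counts rose, but less than in proportion to depth. The median slope of log2 count on log2 total was 1.09 for 544 genes with a mean count of 30 to 60. Its 95% bootstrap interval over genes was 1.06 to 1.14. For the 43 genes with a mean count of at least 150 the slope was 0.68 (0.57 to 0.82). Genes were resampled, so the intervals leave out the spread between the 7 libraries. A ceiling on the number of distinct molecular identifiers counted per gene would give a low slope at the top. A spread of deeper libraries over more genes was predicted to give a low slope at moderate counts too, which was not seen. This cannot decide against a spread: counts are set against their own total, so low slopes in some genes force higher ones in others. The deepest library had 9273 genes with a count and the shallowest 6044. Fold changes of genes near such a ceiling would be understated; without genes with a mean count over 100, 4 of the 5 lists passed and the unfolded protein response had too few genes left to test. The identifier length is not given in the sources used here, and no biological explanation was tested.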

How the results depend on the processing

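The legacy quasi-likelihood fit, the removal of genes with a mean count over 100 and the covariate were chosen after seeing the data. The counts of 0 genes higher and 0 lower held in all 21 alternatives. The 5 lists became 0 with no low count filter (51 lists tested, so many sparse genes entered). They became 0 with the stricter filter, but only 2 lists kept enough genes, none of the 5, so this says nothing about them. They became 0 with an estimated correlation and 0 with fry. The ribosomal protein and oxidative phosphorylation covariate in place of age left 3 (osteoblast matrix and unfolded protein response lost). The unfolded protein response was also lost with no age term. With 1 library left out the number of lists ranged from 1 to 7, and the lists past the threshold were lower in each of these fits. The replicate numbers did not pair the mice (correlations of same-numbered deviations -0.207, -0.122 and -0.146); with the replicate block 0 genes and 6 lists passed, 4 of them among the 5. Of 40 named genes, 33 kept their direction in every setting run. The others turned: Hmgb1 to 0.0203 with no age term and 0.22 with the replicate block, S100b to 0.42 with the replicate block, and Ccl9 to 0.0755 with limma voom, 0.000350 with total counts only and 0.00714 with no low count filter; the cause was not tested. With 1 library left out the ranges were Hmgb1 -0.36 to 0.21, S100b -1.17 to 0.61, Ccl9 -0.31 to 0.0725, Itgam -0.16 to 0.26, Jag1 -2.64 to 0.00773, Sdf2l1 -2.60 to 0.49, Pdia4 -0.13 to 0.46 and the median of the niche list -0.32 to 0.0544. Removing haemoglobin and related genes dropped 0 tested genes and says nothing. Scaling moved the median log2 fold change by less than 0.1. Depth left levels below 3 counts, 17.7 to 38.9 CPM by library, out of reach.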

Other observations

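No test in this part was chosen after its result was seen, but the genes named here other than Xist were chosen after their values were seen. Of the lists that did not pass camera, fibrillar collagens and bone matrix proteins had a median log2 fold change of -0.39 (adjusted p = 0.0777), insulin and IGF signalling -0.44 (0.160), the hypoxia response -0.20 (0.164), matrix metalloproteinases -0.31 (0.164) and osteocyte genes -0.33 (0.293). Socs2, a feedback inhibitor of growth hormone signalling, had a log2 fold change of -0.97 (SE 0.48), and Hk2, the hexokinase of glycolysis that hypoxia induces, one of -0.62 (SE 0.28). Angiogenic factors and receptors had a median of 0.12 (camera adjusted p = 0.661), but fry's mixed test, which asks for changes in either direction, passed for this list (adjusted p = 0.00663) and for no other. In it Sema3a, a guidance factor that protects bone, stood at 0.79 (SE 0.38) and the growth factor Fgf1 at 0.66 (SE 0.30), while the semaphorin receptor Nrp1 stood at -0.64 (SE 0.41). No member of these lists passed edgeR's test over all genes or adjusted over the list alone.

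Immune response lists did not pass camera either. Type I interferon genes had a median of -0.09 and a mean of 0.00428 with a camera direction of lower (adjusted p = 0.987); Rsad2, an antiviral enzyme, stood at -0.76 (SE 0.35) and Irf9, part of the interferon signalling complex, at 0.52 (SE 0.33). The interferon gamma list had a median of 0.01 and a mean of -0.05, cell cycle genes 0.04 and -0.05, mature neutrophil markers 0.06 and -0.15, all with a camera direction of lower, and monocyte markers -0.02 and 0.06 with a direction of higher (adjusted p from 0.824 to 0.992). Lung epithelium markers had a median of 0.39 (adjusted p = 0.713), with Cdh1 at 0.53 (SE 0.26) and Cldn18 at -0.37 (SE 0.31).

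Counts on sex-linked genes did not give a clear sex for these mice, all recorded as male, and reads assigned to the wrong gene were not ruled out. Xist, which is expressed from the inactive X chromosome of females, had 3 to 27 counts per library, and the Y-linked gene Ddx3y had 9 to 31 and Uty 0 to 3, while the Y-linked genes Eif2s3y and Kdm5d had 0 counts in all 7 libraries.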
